A study of Homo sapiens with 12 samples.

How the data were processed

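Guide RNAs of a pooled CRISPR knockout screen were sequenced in H358 cells, a human lung cancer line. Per the labels' protocols, cells carried the GeCKO v2 library in the lentiCRISPR v2 vector, were seeded 2 days before sorting in 10 dishes of 12000000 cells per sample, and were stained for PD-L1 with an APC-labelled antibody. PD-L1 high and PD-L1 low cells were sorted. DNA of 40000000 unsorted cells was taken for a coverage of 300.0 cells per guide. The 12 samples are 3 pools (PD-L1 high, PD-L1 low, unsorted) by 2 sub-libraries (A and B) by 2 replicates. Sub-libraries hold different guides, 3 per gene in each, and library A also holds 4 guides per microRNA. The grouping follows the labels, and each of the 6 columns of the table stacks a library A sample on a library B sample.

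The values are a signal per guide that the authors made and deposited: reads scaled to 1000000 per sub-library and sample, plus 1. The scaling was read off the deposited values, since within each sub-library they sum to 1000000 once 1 is subtracted. Per the submitters' processing notes, Bowtie 1.0.1 and hg19 were used, and their roles are not given in the sources used here. The low values lie on a grid of equal steps. Depth was worked out by taking 1 step as 1 read, and the limit of 3 reads per guide was set from it. The values were treated as a scaled signal and not as counts.

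Analyses used R 4.3.3 with limma 3.58.1 and the data.table package (version 1.17.8), and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The added 1 was subtracted, values were rescaled to a mean of 100 per guide, and guides were kept where their mean over the samples reached 10% of that of the median guide, which left 55248 guides of library A and 49362 of library B. Log2 of the value plus 5 was averaged over a gene's kept guides within each sub-library, for genes with at least 2 kept guides in both, and each sample was centred on its median gene. This gave 16551 genes.

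Genes were compared with limma's linear model for pool and sub-library over the 12 samples, with 8 residual degrees of freedom and empirical Bayes moderation with a trend. The comparisons were PD-L1 high against unsorted, PD-L1 low against unsorted, and PD-L1 high against PD-L1 low. Log2 ratios are given ± SE with n = 4 per pool. Adjusted p-values of genes, guides and microRNAs come from limma's moderated test with the Benjamini-Hochberg method over all features tested, at a threshold of 0.05. Guides and microRNA targets were tested with n = 2 per pool and sub-library. An interaction of pool and sub-library was tested in the same way.

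Gene lists were tested with camera of the limma package at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 27 lists and 3 comparisons, and again with an estimated correlation. The lists were PD-L1 and its known surface partners, interferon and JAK-STAT activators and inhibitors, heme biosynthesis, heme degradation with export and iron handling, the integrated stress response, translation initiation factors, the EGFR-RAS-MAPK pathway and RAS-MAPK negative regulators. They were also PI3K-AKT-mTOR activators and inhibitors, the KEAP1-NRF2 axis, regulators of PD-L1 stability, NF-kappaB activators and inhibitors, the Hippo pathway, the TGF-beta pathway, chromatin coregulators, N-glycosylation with ER protein entry, MHC class I presentation and tumour suppressors. The last were aminoacyl-tRNA synthetases, cytosolic and mitochondrial ribosomal proteins, proteasome subunits, complex I subunits and olfactory receptors. A count adjusted over the list alone applies Benjamini-Hochberg to the members of that list.

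Genes were named by a rule set before the values were seen. In each comparison these are the 10 with the largest rise and the 10 with the largest fall among genes past the threshold with the same sign in 4 of 4 samples. Where fewer pass, the genes of smallest p with 4 of 4 samples of that sign are added, up to 5 per direction. The 2 highest and 2 lowest members of each list that passed are named too, and CD274, CMTM6, UROD, KEAP1, EIF5B, JAK1, IFNGR1 and IRF1 always. Some genes under this rule are not reported here. Where a gene falls outside the rule the text says so, or names it as a member past the threshold adjusted over its list alone. Gene names are those deposited, and 15282 of the 16551 are current symbols, 1136 match through a synonym and 133 match none. In 24 symbols, covering 144 guides, the name had been turned into a date.

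Evenness was compared between sorted and unsorted pools by exact permutation of the 12 samples. The procedure was tested on simulated data, in which shifts were added to 200 genes after guides had been shuffled among genes. In PD-L1 high against low, 13.4% of genes shifted by 2 on the log2 scale were called, 74.6% of those shifted by 4 and 98.5% of those shifted by 6, and 60 unshifted genes were called. In each comparison with unsorted cells 3 unshifted genes were called. Camera called 10 of 10 shifted lists and 0 of 30 others.

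Alternatives covered the pseudocount, the guide filter, centring, the summary over guides, robust rank aggregation, each sub-library alone, sample weights, a replicate block and leaving out each sample. Those added after seeing the data were 2000000 random sets in robust rank aggregation, a random block, averaged replicates, leaving out both unsorted library A samples, leaving out each sample in turn for the lists, and p-values set against shuffled guides. The filter left out, among others, 6457 guides at 0 in every column. The guide numbering also leaves 1606 numbers of library A and 1903 of library B that are not analysed here.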

Results

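The screen asked which gene knockouts alter the amount of PD-L1, the ligand of the immune checkpoint receptor PD-1, on the surface of H358 cells. H358 is a human lung adenocarcinoma line. Cells carrying the genome-wide GeCKO v2 knockout library were stained for PD-L1 and sorted, and the guide RNAs were sequenced in the PD-L1 high pool, the PD-L1 low pool and unsorted cells. A guide that is more abundant in the high pool marks a knockout found more often in cells with much PD-L1, and a guide that is more abundant in the low pool marks the opposite. The library comes as sub-libraries A and B, which hold different guides against the same genes. Each pool was sequenced for both sub-libraries in 2 replicates, which gave 12 samples and 4 values per gene and pool. Nothing in the labels says that replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

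The table lists 119902 guides, 63777 of library A and 56125 of library B. If 1 step of the low values is 1 read, the samples held between 11.4 and 25.3 times 1000000 reads, and the level that 3 reads stand for lay between 0.118 and 0.263 reads per 1000000 (RPM). Coverage of the library differed between samples. The unsorted samples of library B detected 96.6% and 95.8% of their guides, while those of library A detected 34.8% and 54.2%. The sorted samples detected between 44.4% and 67.7%. Poisson counting around the mean depth would leave no more than 7.87e-125% of guides undetected in either unsorted library A sample. Non-targeting guides were undetected in 59.7% and 39.3% of cases in unsorted library A, against 0.8% and 1.3% in unsorted library B. Over all 12 samples, sorted pools detected 55.8% ± 8.58 of guides (SD, n = 8) and unsorted pools 70.4% ± 30.9 (SD, n = 4), a difference of -14.6 percentage points that did not exceed chance (exact permutation test, two-sided, p = 0.214, adjusted p = 0.6 over 3 measures). The Gini index (0.721 against 0.687, exact p = 0.600) and the share of reads held by the top 1% of guides (9.54% against 11.2%, exact p = 0.448) gave no call over both sub-libraries either. These pooled values average opposite directions. Sorted pools detected 16.0 percentage points more guides than unsorted in library A (exact p = 0.2) and fell by 45.1 points in library B (exact p = 0.0667, the smallest that 2 unsorted samples allow). The Gini index was 0.692 against 0.832 in library A and 0.750 against 0.542 in library B, and the top 1% held 8.59% against 15.8% and 10.5% against 6.66%, each at an exact p of 0.0667.

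**Figure D1:**
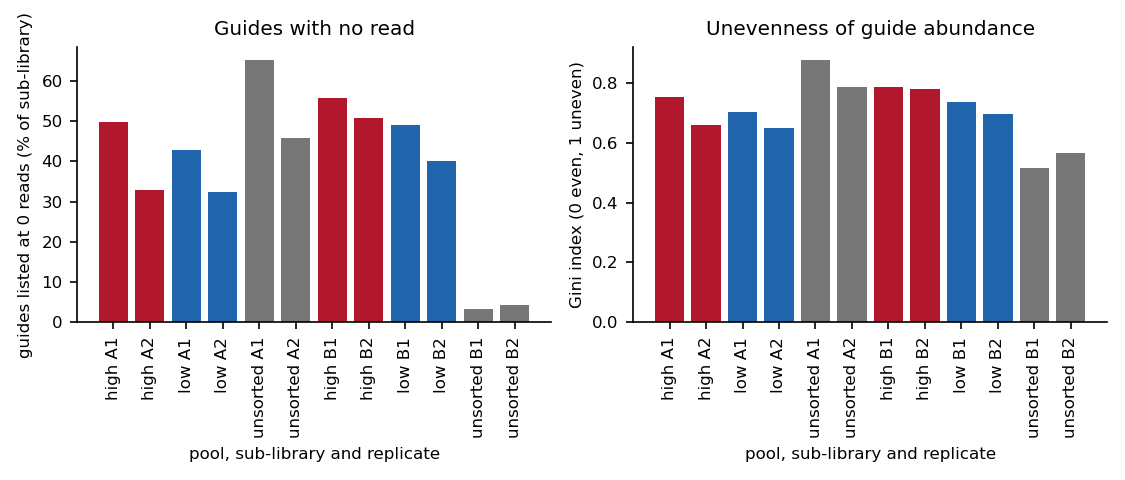
Left, guides listed at 0 reads as a percentage of the sub-library, and right, the Gini index of guide abundance (0 even, 1 uneven), with 1 bar per sample. Red bars are PD-L1 high, blue PD-L1 low and grey unsorted, and the unsorted bars run from 3.39% undetected guides in library B to 65.2% in library A.

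Guide abundance was reproducible only in part. Across kept guides, log2 abundance correlated between the replicates of unsorted library B at r = 0.904 but between those of unsorted library A at 0.140. It correlated between replicates of a sorted pool at a mean r of 0.255 in library A and 0.281 in library B, and between different sorted pools at 0.128 and 0.119. Non-targeting guides, which cut no gene, also correlated more within a sorted pool, with r of 0.254 and 0.354 within a pool against 0.168 and 0.192 between pools. These correlations are across guides within samples, and guides are not independent replicates.

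Guides against fitness genes were scarce before sorting. In unsorted library B, the median guide against cytosolic ribosomal protein genes stood at 17.7 and 16.3 on a scale where the mean guide is 100. Proteasome guides stood at 38.4 and 32.1, guides against olfactory receptors, genes with no role expected in lung cells, at 91.0 and 85.6, and non-targeting guides at 115 and 97.47. In unsorted library A the median guide of the ribosomal and proteasome lists was listed at 0 in both samples, and that of non-targeting guides at 0 and 8.09.

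CD274, the gene that encodes PD-L1, was read first because its guides check the sort. Its 6 guides averaged 0.456 RPM in the PD-L1 high pool, 279.9 in the PD-L1 low pool and 21.05 in unsorted cells. For 4 of the 6 guides both low-pool values exceeded both high-pool values, and for 0 guides the reverse held. The gene's log2 ratio, high against low, was -5.10 ± 0.88 (SE, n = 4 per pool, adjusted p = 0.00158, limma), with the same sign in 4 of 4 samples. The direction is that of the labels of both sorted pools. Against unsorted cells the ratio was -2.65 ± 0.88 in the high pool (adjusted p = 0.404) and 2.45 ± 0.88 in the low pool (adjusted p = 0.936), and neither passed.

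**Figure D2:**
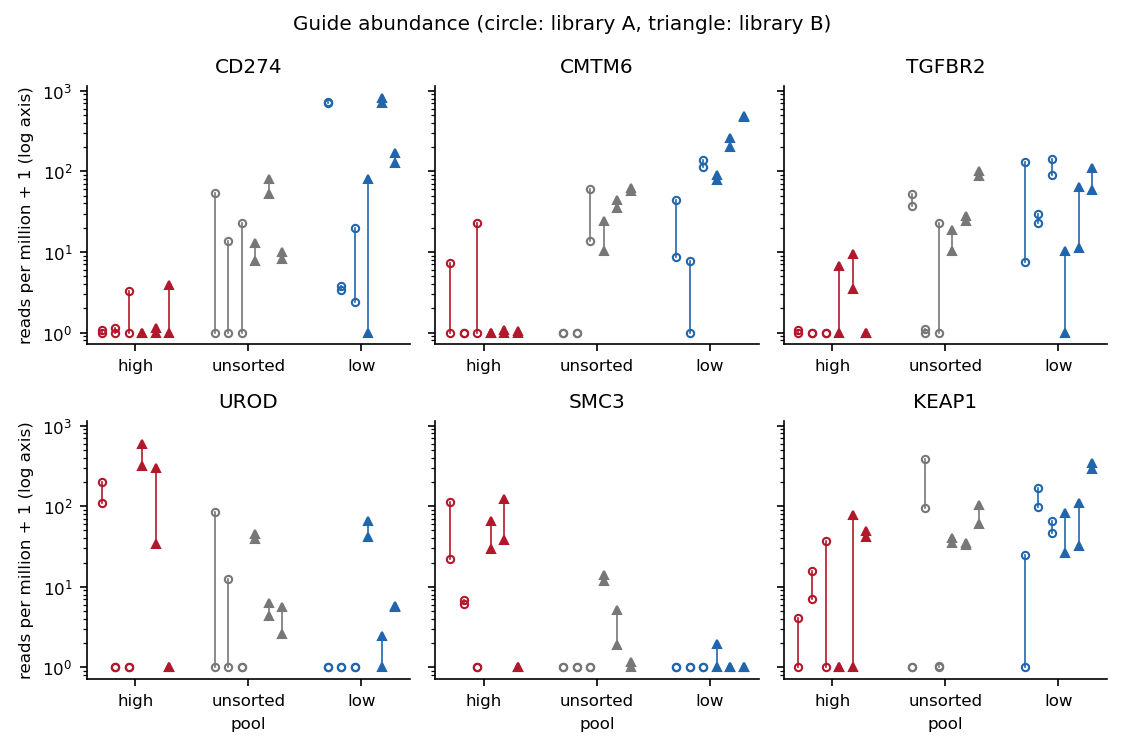
Abundance of each guide in RPM plus 1, on a log axis, for 6 genes in the PD-L1 high (red), unsorted (grey) and PD-L1 low (blue) pools. Each joined pair of points is 1 guide in its 2 replicates, with circles for library A and triangles for library B. CD274 guides average 0.456 RPM in the high pool and 279.9 in the low pool, while UROD guides average 129 and 9.52.

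The comparison of PD-L1 high with PD-L1 low sets pools that were both sorted against each other. Loss of CMTM6, a membrane protein that keeps PD-L1 at the cell surface, was enriched in the low pool, with a log2 ratio of -5.11 ± 0.89 (SE, adjusted p = 0.00158). CMTM6 guides averaged 2.38 RPM in the high pool and 158 in the low pool, and for 5 of 6 both low-pool values exceeded both high-pool values. At the other end, guides against SMC3, a subunit of cohesin, were the most enriched in PD-L1 high cells, at 5.49 ± 0.84 (adjusted p = 0.000226). ENY2, a subunit of the SAGA deubiquitinating module and of the mRNA export complex TREX-2, followed at 4.95 ± 0.87 (adjusted p = 0.00158). SMC3 guides averaged 33.0 RPM in the high pool and 2.42 in unsorted cells. In the low pool they averaged 0.0812 RPM, below the level of 3 reads. Only 2 of the 3 SMC3 guides were kept in each sub-library, and for 4 of 6 both high-pool values exceeded both low-pool values. ENY2 guides averaged 67.5 RPM in the high pool, 2.21 in the low pool and 7.30 in unsorted cells. Genes of N-glycosylation fell as a group. So did the TGF-beta and EGFR-RAS-MAPK lists at the preset correlation, but not with an estimated correlation (adjusted p = 0.152 and 0.122). Of 16551 genes, 45 passed an adjusted p of 0.05, of which 30 were higher and 15 lower in the high pool, and all 45 had the same sign in 4 of 4 samples.

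These 45 calls differ in how far they stand above shuffled guides, a check chosen after the counts were seen. Guides were shuffled among genes 100 times, which keeps every sample's guide values and removes gene effects. A mean of 17.1 genes per shuffle had p-values as small as those of the 45, or 38.0% of their number. Set against the shuffled p-values, 4 genes passed: SMC3, CD274, CMTM6 and ENY2, each with an adjusted p of 0.01. For USP9X and NOP16 that adjusted p was 0.09, for TBL1XR1 and C10orf2 0.109, and for the other 37 genes it lay between 0.112 and 0.357. Robust rank aggregation over guides called 0 genes with 100000 random guide sets. The smallest p it could give was then 1e-05, which 3 genes reached, and its smallest adjusted p was 0.0828. The count of 0 was thus limited by the number of sets. With 2000000 sets, drawn from uniform values and not from the observed guide ranks, it called 3. Of these CD274 and CMTM6 were lower, and SMC1A, a second cohesin subunit, was higher (adjusted p over all genes in limma 0.171, log2 ratio 2.84).

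Other genes with a large rise in the high pool included the deubiquitinase USP9X (4.77 ± 0.92), C10orf2, which encodes the mitochondrial DNA helicase Twinkle (4.50 ± 0.89), the nucleolar protein NOP16 (4.42 ± 0.85) and SNRPA, a protein of the U1 snRNP (4.385 ± 0.88). DNAJC2, a ribosome-associated chaperone (4.29 ± 0.95), COX15, which makes heme A for cytochrome c oxidase (4.27 ± 0.87), and the endocytic protein FCHO2 (4.23 ± 0.89) rose too, with adjusted p-values from 0.00735 for USP9X to 0.0227 for DNAJC2. Beyond the fixed naming rule, and named after their values were seen, 20 more genes rose, with log2 ratios between 3.465 (MED6) and 4.17 (TTI2): COX10, EIF6, CD3EAP, PAK1IP1, NRF1, HDDC2, IGFBP1, TTI2, ARMC7, SLC1A6, EAF1, DPH1, PGAP3, FGFR1OP, CAP1, PRKRIR, PGS1, MED6, ATP5L and VPS13B.

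TBL1XR1, a subunit of the NCoR corepressor complex, fell by 4.50 ± 0.89 (adjusted p = 0.00926), and the actin-binding protein PFN1 by 4.13 ± 0.88 (adjusted p = 0.0153). TGFBR2, the type II receptor of TGF-beta, fell by 4.01 ± 0.88, DPAGT1 by 3.97 ± 0.89, the GTPase-related ARL16 by 3.94 ± 0.90, ALG14 by 3.90 ± 0.89, AMIGO3 by 3.82 ± 0.85 and ALG1 by 3.79 ± 0.86, with adjusted p-values from 0.0217 to 0.0295. TGFBR2 guides averaged 1.38 RPM in the high pool and 55.3 in the low pool, and for 5 of 6 both low-pool values exceeded both high-pool values. SMAD4, the shared transcription factor of TGF-beta signalling, fell by 3.76 ± 0.86 (adjusted p = 0.0285), and PTPN11, the phosphatase SHP2 that couples receptors to RAS, by 3.69 ± 0.87 (adjusted p = 0.0385). NAA35, PSIP1 and GTF3C3, named after their values were seen, were the other 3 genes that fell.

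**Figure D3:**
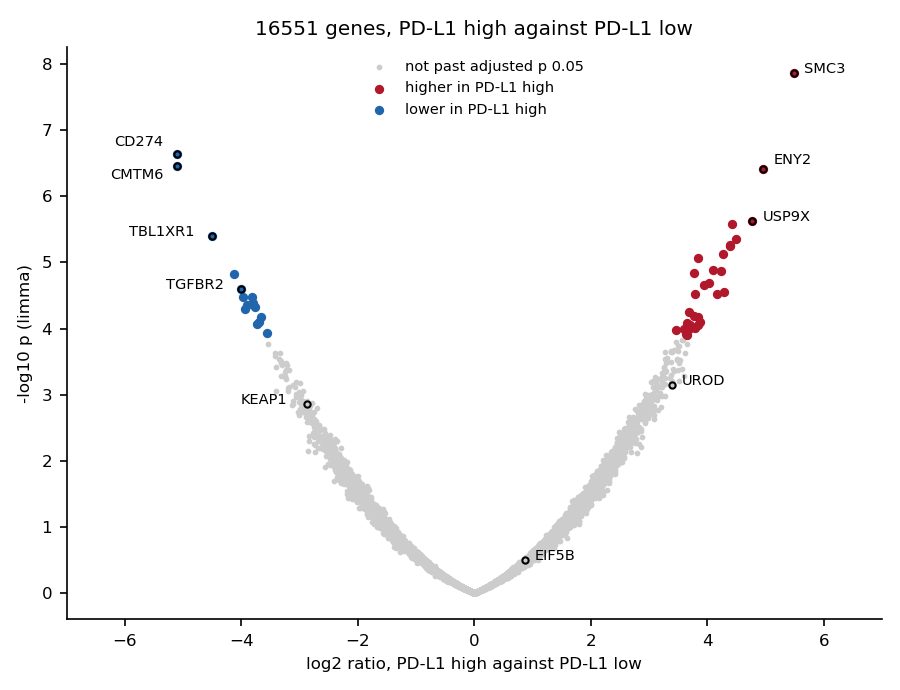
Log2 ratio of PD-L1 high against PD-L1 low (horizontal axis) and -log10 of limma's p (vertical axis) for 16551 genes, 1 point each. Red points are the 30 genes past an adjusted p of 0.05 and higher in PD-L1 high, blue points the 15 that were lower, and grey points did not pass. CD274 and CMTM6 lie together at -5.10 and -5.11, SMC3 at 5.49, and EIF5B at 0.86 among the genes that did not pass.

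Genes that the series title or PD-L1 biology point to mostly missed the threshold. UROD, an enzyme of heme synthesis, had a log2 ratio of 3.39 ± 0.95 (adjusted p = 0.0977) with 4 of 4 samples of that sign. Its guides averaged 129 RPM in the high pool, 9.52 in the low pool and 16.0 in unsorted cells, but both high-pool values exceeded both low-pool values for only 3 of 6 guides, and the reverse held for 1. KEAP1, the adaptor that leads NRF2 to degradation, stood at -2.87 ± 0.86 (adjusted p = 0.125, 4 of 4 samples). EIF5B, the translation initiation factor in the title, stood at 0.86 ± 0.85 (adjusted p = 0.747) with only 2 of 4 samples of that sign, and its guides averaged 4.72 RPM in the high pool, 2.79 in the low pool and 5.80 in unsorted cells. Among members of interferon signalling that did not pass were IFNGR1 at 2.43 (adjusted p = 0.269), JAK1 at 0.04 (0.993) and IRF1 at -0.17 (0.966). At this spread, with a median SE of 0.890, the smallest log2 ratio that passed was 3.465, and of simulated shifts of 2 on the log2 scale 13.4% were called. That share can overstate the power, since the simulated shifts also moved guides at 0 reads in full.

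Among the 27 gene lists fixed beforehand, 4 passed camera's test in this comparison. Loss of N-glycosylation and ER protein entry genes was depleted from PD-L1 high cells: of 46 members 34 had negative ratios, the median was -0.89, and the adjusted p was 6.07e-05 (0.0309 with an estimated correlation). Of its members 3 fell over all genes, DPAGT1, ALG14 and ALG1, which build the lipid-linked oligosaccharide, and 5 passed when adjusted over the list alone, with ALG2 (-3.24) and SPCS3 (-3.41) added. EMC8 (1.62) and ALG12 (1.36) had the highest ratios and did not pass.

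The EGFR-RAS-MAPK list had a median of -1.02 over 21 genes, 15 of them negative (adjusted p = 0.0132, but adjusted p = 0.122 with an estimated correlation). PTPN11 was its 1 member past the threshold over all genes. The adaptor GRB2 (-3.42 ± 0.87, adjusted p = 0.0637) was added when adjusted over the list alone, which made 2, while HRAS (1.43) and MAP2K2 (0.95) had the highest ratios. The TGF-beta list had a median of -0.65 over 11 genes, 7 of them negative (adjusted p = 0.0241, but adjusted p = 0.152 with an estimated correlation). TGFBR2 and SMAD4 fell, SMAD3 (-2.71) was added when adjusted over the list alone, which made 3, and TGFB1 (0.84) and ZEB2 (0.72) were highest. Leaving out each sample in turn moved the median between -1.13 and -0.068 and ended the call in 2 of 12 fits. PD-L1 and its known surface partners had a median of -0.39 over 9 genes (adjusted p = 0.0327, but adjusted p = 0.155 with an estimated correlation). CD274 and CMTM6 were its 2 members past the threshold, over all genes and when adjusted over the list alone, and CD80 (0.94) and B3GNT3 (0.37) were highest. Leaving out each sample moved that median between -0.79 and -0.086 and ended the call in 5 of 12 fits.

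**Figure D4:**
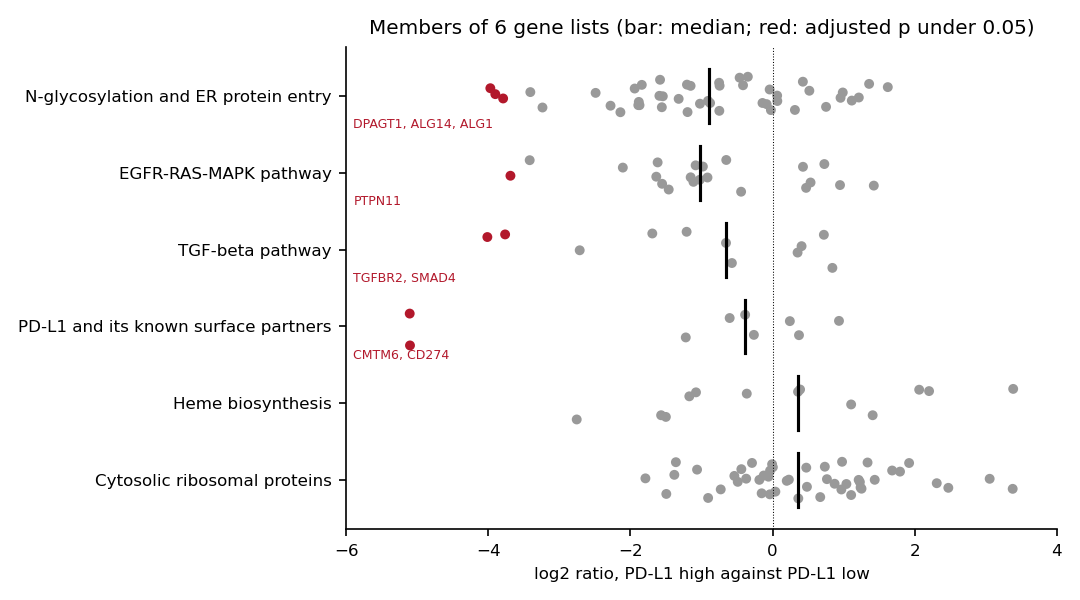
Log2 ratios of PD-L1 high against PD-L1 low for the members of 6 gene lists, 1 point per gene, with a bar at each list's median. Red points are genes past an adjusted p of 0.05 over all genes and are named under each list. The medians run from -1.02 for the EGFR-RAS-MAPK list to 0.36 for heme biosynthesis and for cytosolic ribosomal proteins.

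The other 23 lists did not pass. Heme biosynthesis had a median of 0.36 over 13 genes (adjusted p = 0.907), with UROD higher and SLC25A38 (-2.76) lower when adjusted over the list alone, and heme degradation, export and iron handling had adjusted p = 0.907. The integrated stress response list stood at a median of 0.51 over 20 genes (adjusted p = 0.666), with GCN1L1 (3.43) past the threshold when adjusted over the list alone, and translation initiation factors stood at 0.47 over 32 genes (adjusted p = 0.464), with EIF6 (3.85) past both thresholds. Interferon-gamma and JAK-STAT activators had adjusted p = 0.910 and their inhibitors 0.919, and antigen presentation by MHC class I 0.588. RAS-MAPK negative regulators had adjusted p = 0.588, PI3K-AKT-mTOR activators 0.802 and inhibitors 0.541, the KEAP1-NRF2 axis 0.561, and regulators of PD-L1 stability 0.954. NF-kappaB activators had 0.831 and inhibitors 0.464, the Hippo pathway 0.907, chromatin coregulators 0.954, tumour suppressors 0.954 and aminoacyl-tRNA synthetases 0.685. Cytosolic ribosomal proteins had adjusted p = 0.392, proteasome subunits 0.521, complex I subunits 0.588, mitochondrial ribosomal proteins 0.521 and olfactory receptors 0.918. Adjusted over the list alone, KEAP1, LAMTOR3, RRAGA and MAP3K7 were lower, CHUK, PSMC5, RPLP2 and RPL28 were higher, and among chromatin coregulators 4 were higher (VHL, SMARCB1, CCNC and MAX) and 3 lower (BRD2, KMT2A and CREBBP). For PI3K-AKT-mTOR activators the median (0.19) was positive while the mean (-0.10) and the test were negative, and signs also differed between median, mean and test for iron handling, chromatin coregulators, tumour suppressors and olfactory receptors.

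The scale of the samples moved the balance of calls. Without centring, the median gene's ratio was -0.34, and centred on the non-targeting guides it was 0.64, so ratios are relative to the median gene. The 30 higher and 15 lower genes became 30 and 2 with centring on non-targeting guides, 3 and 6 without centring, and 12 and 12 after quantile normalization. Without the PD-L1 low replicate 1 of library B the count fell to 7, and without the low replicate 2 of library A to 11.

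PD-L1 high cells were next set against unsorted cells. Genes of the cytosolic and of the mitochondrial ribosome were higher in the high pool as lists at the preset correlation, but not with an estimated correlation (adjusted p = 0.167 and 0.122), and no single gene passed. In limma 0 of 16551 genes passed (1281 at an unadjusted p under 0.05, where 828 are expected nominally and shuffled guides gave a mean of 1113), robust rank aggregation also gave 0, and the smallest adjusted p was 0.0815 for SMC3 (4.20 ± 0.84). Behind it, and short of the threshold, came SMARCB1, a core subunit of SWI/SNF (4.18 ± 0.91, adjusted p = 0.198), USP9X (3.94 ± 0.92), ENY2 (3.77 ± 0.87) and the transcription factor NRF1 (3.35 ± 0.80), each at 0.216. The lowest were MICAL2 (-3.54 ± 0.91), the receptor kinase NTRK3 (-3.49 ± 0.87), MORC4 (-3.33 ± 0.90), DYSF (-3.27 ± 0.87) and the receptor kinase LTK (-3.23 ± 0.87), with adjusted p-values from 0.216 to 0.269. CMTM6 stood at -2.40 (adjusted p = 0.509), JAK1 at -1.72 (0.682), KEAP1 at -1.04 (0.822), EIF5B at 0.70 (0.902), IRF1 at 0.84 (0.876), IFNGR1 at 1.49 (0.739) and UROD at 1.87 (0.654).

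The cytosolic ribosomal protein list had a median of 0.38 over 47 genes, 30 of them positive (adjusted p = 0.0407, but adjusted p = 0.167 with an estimated correlation). No member passed over all genes, and 3 passed when adjusted over the list alone: RPL13A (3.49 ± 0.93), RPL28 (3.197 ± 0.90) and RPL32 (3.196 ± 0.88). RPS14 (-2.04) and RPS12 (-1.54) were the lowest. The list's median lay between 0.30 and 0.66 when each sample was left out in turn. The mitochondrial list had a median of 0.45 over 69 genes, 48 of them positive (adjusted p = 0.0432, but adjusted p = 0.122 with an estimated correlation), with 0 genes past either threshold. Its members ran from MRPL11 (-1.24) and MRPL17 (-1.14) to MRPL35 (2.30) and MRPS12 (3.03). Without the 2 thinly covered unsorted samples of library A, a setting chosen after the data were seen, the medians were 0.72 and 0.68 and the adjusted p 0.0649 for both lists, and each call was lost in 7 of the 12 fits that leave out a sample. Guides against cytosolic ribosomal protein genes were scarce before sorting. Of the other 25 lists, with adjusted p from 0.464 to 0.989, single genes passed when adjusted over the list alone in PD-L1 partners (CD274 and CMTM6 lower), translation initiation factors (EIF6 higher), TGF-beta (TGFBR2 and SMAD3 lower) and chromatin coregulators (SMARCB1 higher, KMT2A lower). The TGF-beta list had a median of 0.59 but a mean of -0.36 and a negative test, and signs also differed for heme biosynthesis, RAS-MAPK negative regulators and aminoacyl-tRNA synthetases. The median gene's ratio was -0.36 without centring and -0.68 with centring on non-targeting guides. With quantile normalization 3 genes passed and with sample weights 32, all of them higher in the high pool, while the sum over guides gave 2, both lower.

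In PD-L1 low cells against unsorted cells, guides against N-glycosylation genes were enriched in the low pool, with a median log2 ratio of 0.73 over 46 genes and 34 positive ratios (adjusted p = 0.000194, and 0.0309 with an estimated correlation). When adjusted over the list alone 3 members passed, ALG14 (4.03 ± 0.89), DPAGT1 (3.44 ± 0.89) and DAD1 (2.72 ± 0.83), the last a subunit of the oligosaccharyltransferase, and EMC4 (-1.78) and SSR1 (-1.32) were lowest. This comparison shares the low samples with high against low, and in high against unsorted the list did not pass (median -0.39, adjusted p = 0.521). The EGFR-RAS-MAPK list was higher in the low pool, with a median of 0.41 over 21 genes and 16 positive (adjusted p = 0.0407, but adjusted p = 0.155 with an estimated correlation), and so was the TGF-beta list, with a median of 0.75 over 11 genes and 9 positive (adjusted p = 0.0446, but adjusted p = 0.167 with an estimated correlation). In neither did a member pass, over all genes or when adjusted over the list alone.

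In the EGFR-RAS-MAPK list PTPN11 (2.70) and GRB2 (2.19) were highest and SOS1 (-1.30) lowest. In the TGF-beta list TGFBR1 (2.33) and SMAD4 (2.01) were highest and SKI (-0.64) and TGFB1 (-0.19) lowest. Leaving out each sample moved the medians between 0.22 and 0.95 and between 0.47 and 1.12, and ended the calls in 8 and 9 of 12 fits. Both calls were lost without the 2 unsorted samples of library A, with medians of 0.35 (adjusted p = 0.363) for EGFR-RAS-MAPK and 0.18 (adjusted p = 0.694) for TGF-beta, whereas the N-glycosylation call held in each alternative run for lists. Of 16551 genes, 0 passed in limma (833 at an unadjusted p under 0.05, against 828 expected nominally and a mean of 821 with shuffled guides) and 0 by robust rank aggregation. The highest were ALG14 (adjusted p = 0.446), LOC643355 (3.61 ± 0.91), DPAGT1, TRAPPC3L (3.30 ± 0.85) and TBL1XR1 (3.12 ± 0.89), and the lowest ADAM15 (-3.63 ± 0.94), NFE2L3 (-3.30 ± 0.88), CYP2B6 (-3.26 ± 0.88), LOXL2 (-3.15 ± 0.90) and TAF5L (-3.14 ± 0.88), with adjusted p-values of 0.931 or 0.936 for all but ALG14. CMTM6 stood at 2.70, KEAP1 at 1.82, IRF1 at 1.01, EIF5B at -0.16, IFNGR1 at -0.94, UROD at -1.52 and JAK1 at -1.75, and none passed.

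Of the other 24 lists, with adjusted p from 0.166 to 0.941, CD274 and CMTM6 were higher and GCN1L1 (-3.03) lower when adjusted over the list alone. Signs of median and test differed for chromatin coregulators, MHC class I presentation and cytosolic ribosomal proteins. The median gene's ratio was -0.02 without centring and -1.31 with centring on non-targeting guides.

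At the level of single guides, loss from the sorted pools dominated. Of 104610 guides, 2919 passed in PD-L1 high against unsorted, 12 higher and 2907 lower, and 2724 in PD-L1 low against unsorted, 11 higher and 2713 lower (limma, n = 2 per pool and sub-library). Library B held 2904 and 2712 of the lower guides, and 2719 and 2609 of them were listed at 0 in both sorted samples. Non-targeting guides passed at nearly the rate of all guides, 2.35% against 2.79% in the high pool and 2.09% against 2.60% in the low pool. With a pseudocount of 20 both counts were 0. Between PD-L1 high and low 0 guides passed in limma (14485 at an unadjusted p under 0.05), and no other tool was run on single guides.

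Library A also targets microRNA genes, of which 1580 were tested with 2 samples per pool. In PD-L1 high against unsorted, guides against hsa-mir-516b-2 were lower by a log2 ratio of -5.79 ± 1.27 (adjusted p = 0.0286). In PD-L1 low against unsorted, 4 were lower, hsa-mir-7849 (-5.71 ± 1.29), hsa-mir-1297 (-5.67 ± 1.32), hsa-mir-1252 (-5.05 ± 1.20) and hsa-mir-4423 (-4.37 ± 1.03), each with adjusted p = 0.0282. The 1 and 4 calls became 0 and 1 with a pseudocount of 1, and 0 and 0 with 20. Between high and low 0 passed in limma (117 at an unadjusted p under 0.05, 79 expected). These 5 microRNAs were named after their values were seen, and each rests on the thinly covered unsorted samples of library A.

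Whether the guide sets of a gene gave different effects was tested as an interaction of pool and sub-library. In limma 0 genes passed in any of the 3 comparisons (1301, 976 and 1922 at an unadjusted p under 0.05 for high against unsorted, low against unsorted and high against low, where 828 are expected). Over the 94 tests of named genes the smallest adjusted p was 0.138. CD274 ratios in high against low were of the same sign in both sub-libraries, at -4.39 with library A alone and -5.82 with library B alone.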

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

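The test of gene effects shared by the sub-libraries, the splits for the comparisons with unsorted cells, and the p-values set against shuffled guides were chosen after the results were seen. Of 109 groups of samples searched for a value far from the others, 4 held one, where chance alone gives about 5.45. A guide against ZDHHC19 took 1.44947% of reads in unsorted library A replicate 2 (Wilson 95% interval 1.44403 to 1.45492, covering counting error only), against 0.0337% to 0.0890% for the top guide of the other unsorted samples. The MRPS12 difference between PD-L1 high and unsorted was 1.232 in library A replicate 1 and 3.405 to 3.779 in the others. The TGFBR1 difference between PD-L1 low and unsorted was 0.7712 in library B replicate 1 and 2.772 to 2.916 in the others. The C10orf2 difference between PD-L1 high and low was 5.962 in library B replicate 1 and 3.869 to 4.200 in the others.

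The first pattern weighed is the 45 genes that separated PD-L1 high from PD-L1 low cells. Chance combinations of drifting guides as the whole cause are argued against by 100 shuffles of guides among genes. With p-values adjusted within each shuffle, these gave a mean of 2.29 calls and at most 14. At the p-value cut of the 45 genes they gave a mean of 17.1 genes and at most 28. Among splits of the 8 samples, the real split gave 31 genes and the highest other 1, so 1 of 34 splits reached it. This decides little about a chance division of the samples, because most other splits part the replicates of a pool. Replicates of a pool share drift, since non-targeting guides also correlated more within a sorted pool than between pools. Effects of the targeted genes may account for part of the calls, since the log2 ratios of libraries A and B correlated at r = 0.0397 across genes, above the highest of 1000 permutations (0.0280). The correlation is weak, and without the 45 genes, which share their sign across libraries by selection, it was 0.0234, above the central 95% of the permutations (-0.0157 to 0.0149) and below the highest. Only SMC3, CD274, CMTM6 and ENY2 passed with p-values set against shuffled guides, so the other genes stay open. The shuffle does not reproduce drift of genes whose guides are all scarce, so it does not exclude drift for SMC3 and ENY2 either. SMC3 and ENY2 each lost their call in 5 of 30 alternatives, CD274 in 4 of 31 and CMTM6 in 3 of 31. The sum over guides gave 0 higher genes and so called neither SMC3 nor ENY2. Robust rank aggregation with 2000000 sets also called neither of them.

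In both comparisons with unsorted cells the count of 0 genes was reached by 34 of 34 splits, with 0 in the highest other, and since any split reaches 0 this decides nothing.

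The second pattern is the higher ratio of ribosomal protein genes in PD-L1 high than in unsorted cells. Low starting abundance of their guides could account for it in both lists. The cytosolic median of 0.38 lay at the 35.35 percentile of abundance-matched random lists (matched median 0.45). The mitochondrial median of 0.45 lay at the 94.71 percentile, high in but inside the matched central 95% (-0.019 to 0.497). The matching uses the same unsorted samples that the ratio is set against. Values that are low there by chance raise the matched medians, which tilts the test toward low abundance, so it cannot decide the question. The 2 thinly covered unsorted samples of library A as the whole cause are argued against, since without them the medians were 0.72 and 0.6831, with unadjusted p = 0.00573 and 0.00641. An effect of ribosomal gene loss on PD-L1 stays open and untested.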

How the results depend on the processing

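The random block, averaged replicates, omission of both unsorted library A samples, 2000000 random sets, shuffled-guide p-values and list fits without each sample were chosen after seeing the data. Where a value moved, the cause was not tested, except that single sub-libraries and left-out samples hold fewer values. The count-based tests planned for recoverable whole reads were not run, because the values were treated as a scaled signal. At this depth counting error alone would leave almost no guide undetected, so uneven coverage of the library limits which guides are seen.

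The 45 genes of PD-L1 high against low became 29 with guides kept at 30% of the median guide, 9 without centring and 24 with quantile normalization. They became 16 with the median over guides (15 higher, 1 lower) and 3 with the sum over guides (0 higher, 3 lower). Library A alone gave 2 and library B alone 0. Robust rank aggregation gave 0, and 3 with 2000000 random sets. Averaged replicates gave 13 and shuffled-guide p-values 4. Leaving out each sample gave 7 to 45. High against unsorted became 3 with quantile normalization, 2 with the sum over guides and 32 with sample weights, and low against unsorted 2 with library A alone and 2 with sample weights; leaving out each sample gave 0 to 0 in both. CD274 kept its direction throughout and lost its call with the median over guides (-4.50, adjusted p = 0.116), library A alone (-4.385, adjusted p = 0.314) and library B alone (-5.82, adjusted p = 0.0956). Robust rank aggregation (-4.78) gave an adjusted p of 0.0828, the smallest it reached in this comparison with 100000 sets, and 0.0248, past the threshold, with 2000000. Leaving out each sample gave -5.59 to -4.45, past the threshold in all 12 fits.

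Guides against unsorted cells fell to 0 and 0 with a pseudocount of 20, and rose to 6622 and 5495 without a filter. MicroRNA targets became 0 and 1 with a pseudocount of 1, and 0 and 0 with 20. The 2, 3 and 4 lists became 0, 1 and 1 with estimated correlation, 0, 1 and 4 with a pseudocount of 1, and 0, 2 and 3 without both unsorted library A samples. Leaving out each sample gave 0 to 2, 1 to 3 and 1 to 4 lists. The N-glycosylation list kept both calls in these, with quantile normalization, a pseudocount of 20, averaged replicates and the block. Lists were not run with other centring, filters, summaries over guides, weights or a single sub-library. Detected guides, unsorted minus sorted, went from 14.6 to 9.91 percentage points with a limit of 10% of the median guide.

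With the replicate block 45 genes passed in PD-L1 high against low, 44 of them shared, and 0 in the other comparisons. The lists stayed at 2, 3 and 4, and guides against unsorted cells became 0 and 0. Deviations of same-numbered samples correlated between -0.0418 and 0.0118, so no pairing by number was seen. Replicates of the sorted pools correlated weakly, so a shared culture or sort could go unseen.

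Ratios that changed sign all belong to genes that did not pass. In high against low, JAK1 was -0.083 with a pseudocount of 20, -0.016 without a filter, -0.37 without centring, -0.20 with quantile normalization, -0.90 with the sum, -2.34 with library A and -0.059 with sample weights, and -0.82 to 0.71 without each sample. IRF1 was 0.40 with control centring, 0.22 with the median and 0.091 with library A, and -0.84 to 0.30 without each sample. B3GNT3 was -0.032 without centring, -1.65 with library A and -2.02 with rank aggregation at either number of sets, and -0.31 to 1.21 without each sample. MAP2K2 was -0.32 with library A and -0.97 with rank aggregation, CD80 -0.14 and -0.42, and EMC8 -0.076 with library A. TGFB1 was -0.095 with the sum and -1.83 with library B, ZEB2 -0.38 with library B, and EIF5B -0.039 to 1.46 without each sample.

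In high against unsorted, EIF5B was -0.0048 with control centring and -0.88 with library A, and -0.20 to 1.30 without each sample, and JAK1 was 0.13 with library B. In low against unsorted, EIF5B was 0.77 with library B, 0.55 with sample weights, 1.14 with rank aggregation and 1.10 without both unsorted library A samples, and -0.57 to 0.35 without each sample. TGFB1 was 1.10 with library B and 0.13 with rank aggregation, and -1.49 to 0.49 without each sample. SKI was -1.68 to 0.20 without each sample. IRF1 was -0.26 with control centring and IFNGR1 0.11 with library A. UROD was 0.82 with library B and 0.52 without both unsorted library A samples, and EMC4 0.22 without both.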

Other observations

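The lists of complex IV assembly, ribosome biogenesis and GPI anchor synthesis were drawn up after the genes that passed were seen, and their tests leave those genes out. COX10 (3.94) and COX15 (4.27), the enzymes that turn heme into heme A for cytochrome c oxidase, were both higher in PD-L1 high than in PD-L1 low cells. The hypothesis that loss of complex IV raises PD-L1 predicts the same of its other genes. Of 27 other complex IV assembly genes 23 had positive ratios, with a median of 0.75 (camera p = 0.00481, 0.0225 with an estimated correlation, adjusted p = 0.00721 over 3 lists), led by COX8A (3.09), COX5A (2.94) and COA5 (2.48). The median lay at the 98.92 percentile of abundance-matched lists, whose central 95% ran from -0.41 to 0.65. That is short of the limit set for ribosome biogenesis, so low guide abundance of these genes stays undecided. The direction is the one predicted, but the hypothesis was found and tested in the same samples. Complex I subunits also had a positive median without passing (0.40, camera adjusted p = 0.588), so a positive median is not particular to complex IV.

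The third pattern weighed is ribosome production. NOP16, CD3EAP (a subunit of RNA polymerase I), PAK1IP1 and EIF6, which act in ribosome assembly, were all higher in PD-L1 high cells. Of 105 other ribosome biogenesis genes 79 had positive ratios, with a median of 0.81 (camera p = 2.155e-07, 0.000162 with an estimated correlation, adjusted p = 6.465e-07 over 3 lists), led by TEX10 (3.29), BOP1 (3.28) and NOL8 (3.24). Low guide abundance, as measured in the unsorted samples, is argued against, since the median lay at percentile 100 of matched lists, whose central 95% ran from -0.16 to 0.40. The matching is imprecise, because it rests in part on unsorted library A, whose replicates correlated at r = 0.140. It therefore does not exclude low abundance. The cytosolic ribosomal protein list did not pass in this comparison (median 0.36, camera adjusted p = 0.392). Proteasome subunits (median 0.24), complex I subunits (0.40), mitochondrial ribosomal proteins (0.39) and aminoacyl-tRNA synthetases (0.54) also had positive medians and did not pass. The median of olfactory receptors was 0.02. A positive median is therefore not particular to ribosome biogenesis. A larger or slower-growing cell that holds more PD-L1 for that reason was not tested. A specific effect on PD-L1 may or may not underlie the rise of ribosome biogenesis genes.

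PIGK, a subunit of the GPI transamidase, held the most abundant guide of both library A samples of the PD-L1 low pool, at 0.0812% (Wilson 95% interval 0.0800 to 0.0825) and 0.0852% (0.0838 to 0.0868) of reads. Its log2 ratio was -1.84 (adjusted p = 0.387). Of 24 other genes of GPI anchor synthesis 16 had negative ratios, with a median of -0.45 (camera p = 0.1254, 0.128 with an estimated correlation). PGAP3, the member of that list that passed and was left out of the test, went the other way (3.71), which leaves the hypothesis of a GPI-anchored regulator undecided.

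Other cohesin genes, looked up after SMC3 was seen, had ratios in PD-L1 high against low of 2.84 for SMC1A, 2.38 for PDS5A, 2.18 for NIPBL, 1.14 for STAG2, 1.07 for MAU2, 1.01 for RAD21 and 0.32 for STAG1, and none passed in limma.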
